A study of Mus musculus with 4 samples.

How the data were processed

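RNA was sequenced from 4 pools of Achilles tendon, 1 per group: sham and tenotomy at 7 days and at 6 months of age. Per the labels' protocols, the RNA integrity values were below 8, libraries were made from 10 ng of RNA with a directional kit after ribosomal RNA depletion, and paired 75-base reads were made on a MiSeq. The submitters' processing notes name TopHat, Cufflinks and the mm10 assembly without versions or roles. The gene annotation and the settings are not given in the sources used here. Per the labels' protocols, the authors called differential expression by an exact test after normalization. Whether the p-values and q-values in the authors' deposited tables come from that test is not given in the sources used here, so the calls are printed as deposited.

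The authors deposited 2 gene tables, 1 per age, with 23351 lines each and the layout of a Cuffdiff gene comparison. Their expression values were taken as FPKM from that layout and from Cufflinks being named, since they are not whole numbers and do not sum to the same total in each library. Any scaling between the 2 libraries of a table is not given in the sources used here. The p-values and q-values in the authors' deposited tables, per the file headers, come with a status for each gene. The deposited fold column held text where tenotomy FPKM was 0, so ratios were recomputed from FPKM, with a largest gap to the deposited numbers of 4.83e-05. With a single pool per group, the authors' p-values do not hold the spread between animals. The labels of the tenotomy pools also speak of uninjured tendon; the pools were grouped by the operation that the same labels name.

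Log2 ratios were computed with a pseudocount of 1 FPKM over genes at or above 5 FPKM in either library, and genes with an absolute log2 ratio of at least 1 are called higher or lower. A gene low in both libraries is left out. Lists of low genes can therefore show a larger share past 2-fold than all their listed members would. No test was made, since there are no replicates. The difference between ages was the 7-day log2 ratio minus the 6-month log2 ratio, over genes at or above 5 FPKM in any library. For 29 gene lists, the median log2 ratio was given with its percentile among 10000 random lists of the same size drawn from 20 bins of mean expression; lists at or below 2.5 or at or above 97.5 were taken as standing apart. Of the listed symbols, 484 were found in the tables and 5 were not (Ly6g, Trbc2, Snorc, Ahsp and Flg). Another 8 lists, for muscle fibre types, metabolic paralogs, denervation, imprinted genes, histones and hair, were chosen after the data were seen and are used only in the closing section and for the hair share.

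The genes named were set before the data were examined. They are the 10 highest and 10 lowest ratios at each age and for the difference, among single-gene entries at or above 10 FPKM without small RNAs, mitochondrially encoded and predicted genes, the up to 4 members of each list with the largest ratios past 2-fold, and 15 genes given whatever their values; some genes under this rule are not reported here. Adipoq, Ccl7, Ctgf, Fabp4, Fibin, Irs1, Slc9b2, Sox9 and the genes named for the added lists were chosen after their values were seen. Gene positions came from GENCODE M21, in which 181 of 186 named genes were matched.

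Depth was worked out from the FPKM of single-transcript genes of at least 800 bp, whose low values came out as whole fragments within 0.1 for 77.2%, 74.4%, 72.6% and 73.1% of genes in the 7-day sham, 7-day tenotomy, 6-month sham and 6-month tenotomy libraries. Poisson draws at those depths passed 2-fold by counting error alone in 0.231% (higher) and 0.186% (lower) of 644 genes at 7 days, where 10.2% and 19.7% were observed. At 6 months they did so in 0.482% and 0.381% of 577 genes, where 15.1% and 20.5% were observed. These values cover counting error only. Simulated data were drawn at a single depth for all libraries, not at the depth of each. There the rule found 100% of genes set 4-fold apart and 96% of those set 3-fold apart among the 644 genes of 7 days. Among the 577 genes of 6 months it found 100% and 95%. The 6-month sham library was shallower than the simulated depth, so the 6-month values may be too favourable. Unchanged genes were called in 0.676% and 0.265%, and unshifted lists of 12 genes stood apart in 5% and 7.5% of draws.

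The 12 alternatives set in advance changed the pseudocount, the floor, the scaling, the entries used and the list members, or took the authors' call. A further 2 were added after seeing the data, a scaling without muscle genes and small RNAs and the removal of muscle genes with every gene at least 8-fold lower at 7 days. Work was done in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.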

Results

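Gene expression was measured by RNA sequencing in the Achilles tendon of male Scx-EGFP mice, a C57BL/6 line in which green fluorescent protein reports expression of the tendon transcription factor Scx. The right tendon was transected (tenotomy) and a sham operation was done on the left hindlimb, in neonates at 7 days of age and in adults at 6 months of age. RNA was collected 5 days after the operation. After tenotomy the distal stump was taken without the connective tissue around it. RNA was pooled from 11 mice in each 7-day group, 5 mice in the 6-month sham group and 9 mice in the 6-month tenotomy group, and each pool gave 1 library. The series asks how phosphoinositide 3-kinase (PI3K) and Akt signalling acts in Scx-lineage tenocytes and Tppp3-lineage sheath cells during tendon regeneration. The libraries here let tendon, sheath and PI3K-Akt genes be set beside those of the other cell types in the injured tissue.

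The steps between low FPKM values (fragments per kilobase of transcript, scaled to library size) implied about 2670000 fragments in the 7-day sham library and 3290000 fragments in the 7-day tenotomy library. The 6-month libraries held about 1780000 fragments (sham) and 2430000 fragments (tenotomy). A 2 kb transcript at 5 FPKM was thus seen in about 26.7, 32.9, 17.8 and 24.3 fragments, in the same order. Ratios are log2((tenotomy FPKM + 1)/(sham FPKM + 1)), a scale that understates differences of low genes, and folds are on the same scale. Because each group was 1 pool, the spread between animals was not measured and none of the differences below has a replicate check.

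Skeletal muscle transcripts were abundant in 3 of the 4 libraries. The 22 mature muscle genes made up 6.41% of the FPKM of ordinary genes in the 7-day sham library and 0.0154% in the 7-day tenotomy library. At 6 months they made up 14.8% after sham and 5.90% after tenotomy. Acta1, the skeletal muscle actin, stood at 6925, 9.71, 9234 and 1516 FPKM in these libraries. Hair keratins and keratin-associated proteins made up 0.384% in the 7-day sham library, 0.0127% in the 7-day tenotomy library and 0% at 6 months. Small structural RNAs took 28.6%, 27.3%, 41.3% and 51.7% of all FPKM.

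In neonates, 12 of 15 activated fibroblast genes, 15 of 20 macrophage genes and 11 of 21 matrix remodelling genes were at least 2-fold higher in the tenotomy library, and all 22 mature skeletal muscle genes were lower. Mmp13, a collagenase, was 22.3-fold higher (1.51 FPKM after sham, 54.9 after tenotomy), and Tnn, the matrix glycoprotein tenascin-W, was 15.8-fold higher (5.00 and 93.9 FPKM). Postn (periostin), the most abundant gene of the activated fibroblast list after tenotomy, stood at 592 FPKM after sham and 2815 after tenotomy. Ckm, muscle creatine kinase, stood at 892 and 0.25 FPKM. Of 9424 genes at or above 5 FPKM in either library, 523 were at least 2-fold higher and 973 at least 2-fold lower after tenotomy.

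Of 15 genes of activated fibroblasts, 12 were at least 2-fold higher at 7 days and none was 2-fold lower, with a median log2 ratio of 1.85. The highest were Tnn, Tnc (tenascin-C, 58.1 and 381 FPKM), Ltbp2 (3.22 and 21.7 FPKM) and Postn, while Ctgf was lower without passing 2-fold (116 and 75.6 FPKM). Among 21 matrix proteases, inhibitors and crosslinking enzymes, 11 were higher and none lower (median 1.02). Mmp2 (gelatinase A) stood at 110 and 477 FPKM, Mmp14 (its membrane-bound activator) at 108 and 470 FPKM, and Mmp11 at 2.55 and 11.7 FPKM. Of 19 matrix ligands and integrins that act upstream of PI3K, 8 were higher and 1 lower (median 0.59). Spp1 (osteopontin) was 7.19-fold higher, Itga11 (a collagen-binding integrin subunit) stood at 9.87 and 49.3 FPKM, and Fn1 (fibronectin) at 321 and 1391 FPKM, whereas the laminin gene Lama2 stood at 21.3 and 8.35 FPKM.

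Most macrophage and osteoclast genes measured were higher in the same library. Of 20 macrophage and monocyte genes, 15 were at least 2-fold higher at 7 days (median 1.32). Examples were Cd52 (5.86 and 41.0 FPKM), Ctss (cathepsin S, 26.3 and 148 FPKM), Gpnmb (3.11 and 19.2 FPKM) and Trem2 (4.55 and 20.5 FPKM). The 3 neutrophil genes measured of 11 listed, S100a8, S100a9 and Ngp, were all higher (median 1.80). So were 4 of 5 osteoclast genes (median 1.46), among them Mmp9 (4.19 and 50.3 FPKM) and Acp5 (18.6 and 52.2 FPKM). Of 6 cytokine genes at the expression floor, 2 were higher (median 0.85), Cxcl12 (61.6 and 167 FPKM) and Ccl2 (2.41 and 7.94 FPKM). Of 7 interferon-stimulated genes, 3 were higher (Ifit3, Irf7 and Bst2; median 0.72). Among vessel genes, 2 of 12 endothelial genes were higher (Vwf and Emcn; median 0.57), and 3 of 10 mural genes were (median 0.66).

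Tendon genes went both ways at 7 days. Of 18 tenocyte and tendon-enriched genes, 7 were at least 2-fold higher, 3 lower and 8 within 2-fold (median 0.10). The small proteoglycan genes Aspn (131 and 512 FPKM) and Lum (118 and 453 FPKM) were highest, and Chad (27.1 and 8.36 FPKM) and Cilp2 (82.6 and 29.3 FPKM) were lowest. Scx stood at 24.8 and 23.3 FPKM, the tendon homeobox gene Mkx at 33.7 and 20.3 FPKM, and the tenocyte membrane protein gene Tnmd at 301.1 and 279 FPKM. Of 14 collagens, 3 were higher (Col12a1, Col5a1 and Col5a2) and none lower (median 0.40). The main tendon collagen Col1a1 stood at 22438 and 13215 FPKM and Col3a1, a collagen of early repair tissue, at 2449 and 4607 FPKM. Of 13 sheath and synovial genes, 2 were higher and 3 lower (median -0.12). Tppp3, which marks the sheath lineage of the series, was 3.30-fold lower (227 and 68.2 FPKM), Clic5 stood at 31.5 and 5.54 FPKM, and Prg4 (lubricin) was 2.44-fold higher (31.9 and 79.4 FPKM). After tenotomy the stump was taken without the connective tissue around it. Lower sheath genes therefore cannot be told apart from less sheath tissue in the pool.

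Transcripts of PI3K-Akt pathway genes differed little in neonates, and the activity of the pathway was not measured. Among all 9424 genes tested, 523 were higher and 973 lower, so most genes lay within 2-fold. Of 23 kinases, regulators and effectors measured, 1 was at least 2-fold higher (Pik3ap1, 4.48 and 10.2 FPKM), none was 2-fold lower and 22 lay within 2-fold (median -0.19, which turned to 0.05 when FPKM was rescaled to a common sum). Akt1 stood at 113 and 99.8 FPKM and Akt2 at 60.4 and 41.4 FPKM. The catalytic subunit genes Pik3ca (17.2 and 9.91 FPKM) and Pik3cd (2.87 and 4.15 FPKM) were within 2-fold. Among 31 growth factor and receptor genes upstream of the pathway, 3 were higher and 1 lower (median 0.36): Hgf (1.31 and 5.48 FPKM), Pdgfrb (17.4 and 43.0 FPKM) and Pdgfc were higher, and Fgf1 (7.66 and 0.904 FPKM) was lower. Pdgfra, a receptor of fibroblast progenitors, stood at 38.5 and 53.2 FPKM. Of 22 TGF-beta and BMP genes, 1 was higher (Ltbp1) and none lower (median -0.02).

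Of 22 cell cycle genes measured at 7 days, 2 were at least 2-fold higher, Plk1 (2.60 and 8.20 FPKM) and Birc5 (4.78 and 11.1 FPKM), and 20 lay within 2-fold (median 0.68). Mki67 stood at 13.4 and 19.2 FPKM. Of 10 cartilage genes, 6 were higher and 3 lower (median 1.35). Acan (aggrecan, 37.2 and 153 FPKM) and Sox9 (3.41 and 11.4 FPKM) were higher, while Col2a1 (110 and 31.7 FPKM) and Col11a2 (182 and 44.3 FPKM) were lower. With a floor of 20 FPKM the median of this list was -1.77, but few genes remained there, and Acan among them was still higher. The direction of the list thus depended on the floor. Of 3 bone-forming genes, 1 was higher, Runx2 (1.02 and 5.42 FPKM), with a list median of -0.24. Of 10 immediate early genes, 2 were higher and 1 lower (median 0.21): Junb (10.9 and 29.3 FPKM) and Ier3 were higher, and Atf3 (28.3 and 4.79 FPKM) was lower.

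The lower side at 7 days was led by muscle. All 22 mature muscle genes were at least 2-fold lower, with a median of -7.51. The 10 lowest named genes were all of skeletal muscle, among them Myh1 (868 and 0.577 FPKM), Mylpf (4241 and 10.8 FPKM) and Myl3, which was listed at 0 after tenotomy and at 468 FPKM after sham. Of 5 genes of developing muscle, 4 were lower (median -3.23), among them the perinatal myosin gene Myh8 (233 and 1.69 FPKM) and the myogenic regulator Myog (15.0 and 0.711 FPKM). Of 17 respiratory chain genes, 15 were lower (median -1.58), and of 18 glycolysis and hypoxia genes, 6 were lower and 1 higher (median -0.71). These lists moved with the muscle share of the libraries given above. Of 12 adipocyte genes, 9 were lower (median -1.28), such as Fabp4 (1232 and 484 FPKM) and Adipoq (129 and 57.8 FPKM), and of 5 skin epithelium genes, 4 were (median -1.70). Of 5 erythroid genes, 4 were lower (median -1.25), but the near-identical globin copies share reads and their separate values are uncertain.

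The list medians at 7 days were compared with those of 10000 random lists matched on size and mean expression, as a description of these libraries. Activated fibroblast, macrophage, remodelling and proliferation genes lay at or near the 100th percentile, and the mature muscle, adipocyte, respiratory chain and glycolysis lists at percentile 0. With a floor of 20 FPKM the proliferation list no longer stood apart. The PI3K-Akt list lay at percentile 5.17, the growth factors and receptors upstream of it at 99.8, the matrix ligands and integrins at 99.95, the tenocyte list at 40.7 and the collagens at 93.1. In the authors' deposited table, 90 genes were called significant at 7 days, 3 of them higher (Gpx3, Mmp9 and Slc9b2) and 87 lower, and 72 of the 90 were listed at 0 in a library. The count of higher genes moved with the processing, from 255 with a pseudocount of 5 FPKM to 1036 with FPKM rescaled to a common sum.

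In adults, most of the cytokine, macrophage, activated fibroblast and cell cycle genes measured were higher in the tenotomy library, and mature muscle genes, both measured bone-forming genes and part of the tendon and cartilage genes were lower. Mmp13 was 19.4-fold higher (1.12 and 40.1 FPKM), and Mest, an imprinted gene of growing mesenchyme, was 12.2-fold higher (5.58 and 79.6 FPKM). Ccl2, a monocyte chemoattractant, was listed at 0 after sham and at 15.5 FPKM after tenotomy. Chad, a leucine-rich repeat protein gene of cartilage and tendon, stood at 936 FPKM after sham and 37.9 after tenotomy, and Comp (cartilage oligomeric matrix protein) at 1443 and 156 FPKM. Of 9001 genes at or above 5 FPKM in either library, 866 were at least 2-fold higher and 1067 at least 2-fold lower after tenotomy.

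Of 20 cytokine genes listed, 11 were measured at 6 months, 10 of them at least 2-fold higher and none lower (median 2.64). Some, such as Ccl2 and Il6, reached the floor only after tenotomy, and genes low in both libraries are not counted. Besides Ccl2, the higher genes included Cxcl5 (1.14 and 21.5 FPKM), Ccl7 (3.68 and 28.7 FPKM) and Il1b (1.96 and 18.2 FPKM), while Il6 was listed at 0 after sham and at 6.01 FPKM after tenotomy. Of 20 macrophage genes, 19 were higher (median 1.77), such as Cd68 (3.42 and 35.5 FPKM), Ctss (29.7 and 235 FPKM) and Gpnmb (3.24 and 27.7 FPKM). All 6 neutrophil genes measured, of 11 listed, were higher (median 2.17), among them S100a8 (11.2 and 68.7 FPKM) and Clec4d (1.46 and 14.5 FPKM). Of 4 osteoclast genes, 3 were higher (median 1.71), including Mmp9 (4.16 and 56.3 FPKM), and of 7 interferon-stimulated genes, 3 were (median 0.85). Of 10 immediate early genes, 4 were higher (median 0.12), among them Fos (7.61 and 21.3 FPKM) and Junb (19.6 and 54.1 FPKM). No lymphocyte or Schwann cell gene of the lists reached 5 FPKM at either age.

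Of 15 activated fibroblast genes, 12 were higher at 6 months (median 2.14), among them Tnn (2.28 and 26.3 FPKM), Postn (133 and 844 FPKM) and Wisp1 (2.54 and 18.6 FPKM). Of 23 remodelling genes, 9 were higher and 2 lower (median 0.82). Adamts4 (0.800 and 7.23 FPKM) and Mmp14 (36.8 and 137 FPKM) were higher, and the protease inhibitor genes Timp3 (180 and 34.4 FPKM) and Timp4 (6.37 and 1.01 FPKM) were lower. Of 20 cell cycle genes, 13 were higher and none lower (median 1.28), with Top2a at 3.43 and 16.9 FPKM, Ccna2 at 3.40 and 13.4 FPKM and Mki67 at 3.94 and 12.1 FPKM. Of 21 matrix ligands and integrins, 3 were higher and 3 lower (median 0.54). Tnc (29.6 and 169 FPKM) was highest, and Itga10 (19.5 and 4.16 FPKM) and Spp1 (1131 and 311 FPKM) were lowest. Of 12 endothelial genes, 2 were higher (median 0.48), and of 6 mural genes 1 was higher and 1 lower (median 0.35).

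Of 18 tenocyte and tendon-enriched genes, 9 were lower in adults after tenotomy, 1 higher (Aspn, 109 and 247 FPKM) and 8 within 2-fold (median -0.99). This list no longer stood apart from matched random lists without Chad, with a floor of 1 FPKM or with no floor. Besides Chad and Comp, the lowest were Cilp2 (95.2 and 6.46 FPKM) and Fmod (fibromodulin, 578 and 116 FPKM). Scx stood at 15.9 and 5.70 FPKM and Mkx at 24.8 and 9.60 FPKM, whereas Tnmd stood at 36.9 and 47.0 FPKM. Of 14 collagens, 1 was higher (Col5a1, 120 and 256 FPKM) and 13 were within 2-fold (median 0.33). Col1a1 stood at 5578 and 5766 FPKM and Col3a1 at 1652 and 2807 FPKM. Of 13 sheath and synovial genes, 3 were higher and 3 lower (median -0.13). Has2, a hyaluronan synthase gene, stood at 1.37 and 12.3 FPKM, Tppp3 at 59.0 and 40.3 FPKM, Pdgfra at 31.1 and 35.8 FPKM, and Prg4 at 544 and 179 FPKM, which was 3.03-fold lower.

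Of 7 cartilage genes, 4 were lower and none higher (median -1.29), with Col2a1 at 77.0 and 20.4 FPKM. Both measured bone-forming genes were lower (median -2.92), Ibsp (bone sialoprotein) at 348 and 41.9 FPKM and Alpl (alkaline phosphatase) at 16.1 and 1.42 FPKM. Of 21 TGF-beta and BMP genes, 1 was higher (Tgfbi) and 5 lower (median -0.34), among them the BMP antagonist gene Grem1 (5.78 and 0.571 FPKM) and the BMP-induced inhibitor gene Smad6 (10.2 and 2.23 FPKM). Cytl1, a cytokine-like gene of chondrocytes (71.3 and 0.529 FPKM), and Myoc (894 and 24.3 FPKM) were among the 10 lowest named genes.

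PI3K-Akt genes again lay mostly within 2-fold at 6 months: 3 of 25 were higher, 1 lower and 21 within 2-fold (median -0.14, and 0.05 when scaled without muscle genes and small RNAs). Among all 9001 genes tested, 866 were higher and 1067 lower, so most genes lay within 2-fold here too. The higher members of the PI3K-Akt list were Inpp5d (5.63 and 18.9 FPKM), Pik3r5 (4.94 and 12.9 FPKM) and Pik3cd (4.51 and 10.5 FPKM), genes used mainly by blood cells. Tsc1, an inhibitor of mTOR signalling, stood at 13.0 and 5.33 FPKM. Akt1 stood at 51.9 and 66.7 FPKM, Akt2 at 76.7 and 43.3 FPKM and Pik3ca at 11.7 and 8.46 FPKM. Of 25 growth factor and receptor genes, 3 were higher and 4 lower (median 0.03). Igf2 stood at 7.96 and 41.1 FPKM, and the insulin receptor substrate genes Irs1 (20.5 and 9.56 FPKM) and Irs2 (13.8 and 5.29 FPKM) were lower.

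All 22 mature muscle genes were lower at 6 months too (median -1.68), beside the muscle shares given above. Slow-fibre genes were among the lowest, with Myl2 listed at 0 after tenotomy (831 FPKM after sham) and Myh7 at 341 and 0.563 FPKM, while the fast-fibre gene Myl1 stood at 3948 and 1904 FPKM. Genes of developing or regenerating muscle were higher (4 of 7, median 2.25), among them Myog (1.73 and 26.0 FPKM), Myh8 (0.280 and 13.1 FPKM) and Tmem8c (myomaker, 1.09 and 12.7 FPKM). Of 17 respiratory chain genes, 7 were lower (median -0.99), and of 16 glycolysis and hypoxia genes, 7 were lower and 1 higher (median -0.87). Of 10 adipocyte genes, 2 were lower (median 0.35), and both measured skin epithelium genes were lower (median -2.47). Of 3 erythroid entries, 2 were higher and 1 lower, with the same uncertainty between globin copies.

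Against matched random lists at 6 months, macrophage, cytokine, activated fibroblast, proliferation and remodelling genes lay at the 100th percentile, the tenocyte list at 0.180, the cartilage list at 0.0400 and the PI3K-Akt list at 26.5. The growth factors and receptors lay at 65.4 and the matrix ligands and integrins at 99.9. The tenocyte list passed out of the lowest 2.5% when Chad was left out (percentile 3.08, median -0.70). The authors' deposited table called 0 genes significant at 6 months; its lowest q-value was 0.0741, shared by 6 genes. The count of higher genes ranged from 354 with a floor of 20 FPKM to 1333 with a floor of 1 FPKM, and 61.8% of the genes past 2-fold were higher, against 44.8%, when libraries were scaled without muscle genes and small RNAs.

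**Figure D1:**
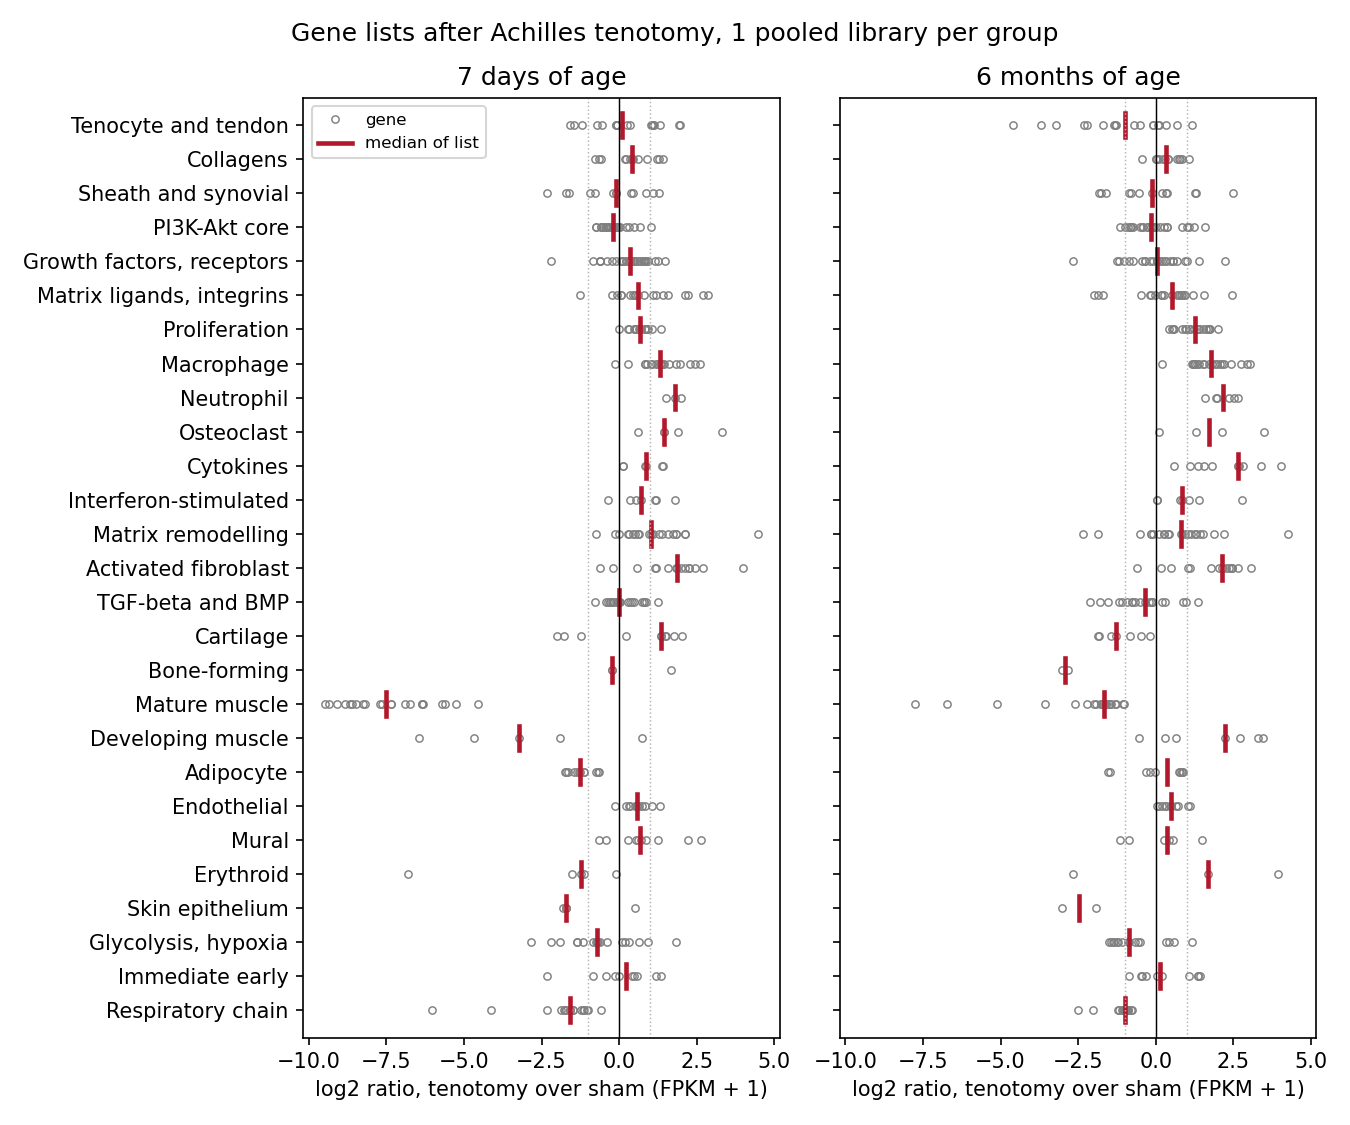
Log2 ratio of tenotomy over sham, on the FPKM + 1 scale, for every gene of each list at or above 5 FPKM at 7 days (left) and 6 months (right). Circles are genes, red bars are list medians and dotted lines mark 2-fold; activated fibroblast genes had medians of 1.85 and 2.14, tenocyte genes 0.10 and -0.99, and mature muscle genes -7.51 and -1.68.

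The ages were compared through their tenotomy ratios, each taken within its own table, since the 2 tables may have been normalized separately. At least 2-fold higher after tenotomy were 12 of 15 activated fibroblast genes at each age and 15 of 20 macrophage genes in neonates and 19 of 20 in adults, while of 18 tenocyte genes 7 were higher and 3 lower in neonates and 1 was higher and 9 lower in adults. Of these 18 genes, 12 had a ratio at least 2-fold higher at 7 days than at 6 months and none the reverse (median difference 1.23). Chad, Comp and Fibin had the largest differences of the list, with log2 ratios of -1.58, 0.35 and 1.04 at 7 days and -4.59, -3.20 and -2.22 at 6 months. Egr1 (-0.76) and Tnmd (-0.45) differed the other way, within 2-fold. Comp stood at 144 and 156 FPKM after tenotomy at 7 days and 6 months, but at 112 and 1443 FPKM after sham. Since the distal stump was taken after tenotomy, the part collected cannot be told apart from the operation in these ratios. Of 10077 genes, the ratio was at least 2-fold higher at 7 days for 568 and at least 2-fold lower for 889. This balance moved to 404 and 1114 genes when libraries were scaled without muscle genes and small RNAs and to 1007 and 1152 genes with FPKM rescaled to a common sum. The common sum also raised the values against the floor and pseudocount. It left 11532 genes against 9424 at the floor at 7 days and 10687 against 9001 at 6 months, so its counts do not reflect scaling alone.

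Other lists whose ratios were higher in neonates were the bone-forming genes (5 of 5, median difference 2.05), the cartilage genes (6 of 11, median difference 1.07), the TGF-beta and BMP genes (6 of 23, median difference 0.55), the remodelling genes (7 of 23, 0.26) and the mural genes (2 of 10, 0.48). Of the 5 bone-forming genes, 3 reached the floor only at 7 days and 2 only at 6 months. Each of their differences thus sets a measured ratio against a ratio of values below the floor, which the pseudocount shrinks. With a floor of 20 FPKM the median difference of the cartilage genes was 0.15. The single genes with the highest differences were Cytl1 (5.48), Galnt15 (5.03), Spp1 (4.70), Clu (4.36) and Ibsp (4.25), all of them lower after tenotomy at 6 months. At 7 days Cytl1 (0.474 FPKM after sham and 0.390 after tenotomy) and Ibsp (1.06 and 3.81 FPKM) lay below the floor in both libraries. Their differences therefore rest mainly on the adult ratios. Lists whose ratios were lower in neonates were the cytokines (6 of 11, median difference -1.70), proliferation genes (4 of 22, -0.51), adipocyte genes (8 of 12, -1.48) and both muscle lists (mature 21 of 22, -5.01; developing 6 of 7, -4.63). Smaller counts passed 2-fold among macrophage genes (3 lower and 1 higher of 20, median difference -0.43), activated fibroblast genes (2 lower and 2 higher of 15, -0.41) and respiratory chain genes (3 of 17 lower, -0.57), while 4 of 6 erythroid entries were lower (-1.80). The lists named so far in this paragraph stood apart from matched random lists, but with a floor of 20 FPKM the proliferation, macrophage, activated fibroblast, cartilage, mural and erythroid lists no longer did. The PI3K-Akt list had 1 of 26 members past 2-fold, Inpp5d (-1.28), and a median difference of 0.04. The muscle shares of the libraries moved with the adipocyte, respiratory chain and muscle lists at 7 days. None of these differences between ages was tested, since each ratio rests on 1 library per group.

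Across the 8348 genes at or above 5 FPKM at both ages, the ratios correlated with Pearson's r of 0.57 and Spearman's rho of 0.63, a correlation across genes, which are not independent replicates. Without the muscle lists, which left 8321 genes, r was 0.58. Other muscle genes, such as Myl2 and Myl3, stayed in, so this does not show how far the correlation rests on muscle. The direction was shared by 72.7% of genes. At least 2-fold higher at both ages were 236 genes, against 38.7 for independent lists of the same sizes, and at least 2-fold lower at both were 500, against 84.5. Mmp13, Tnn, Tnc, Postn, Mmp9 and Ctss belonged to the first group, and the mature muscle genes to the second. Opposite directions past 2-fold were found for 9 genes that were higher in neonates and lower in adults and for 22 with the reverse.

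**Figure D2:**
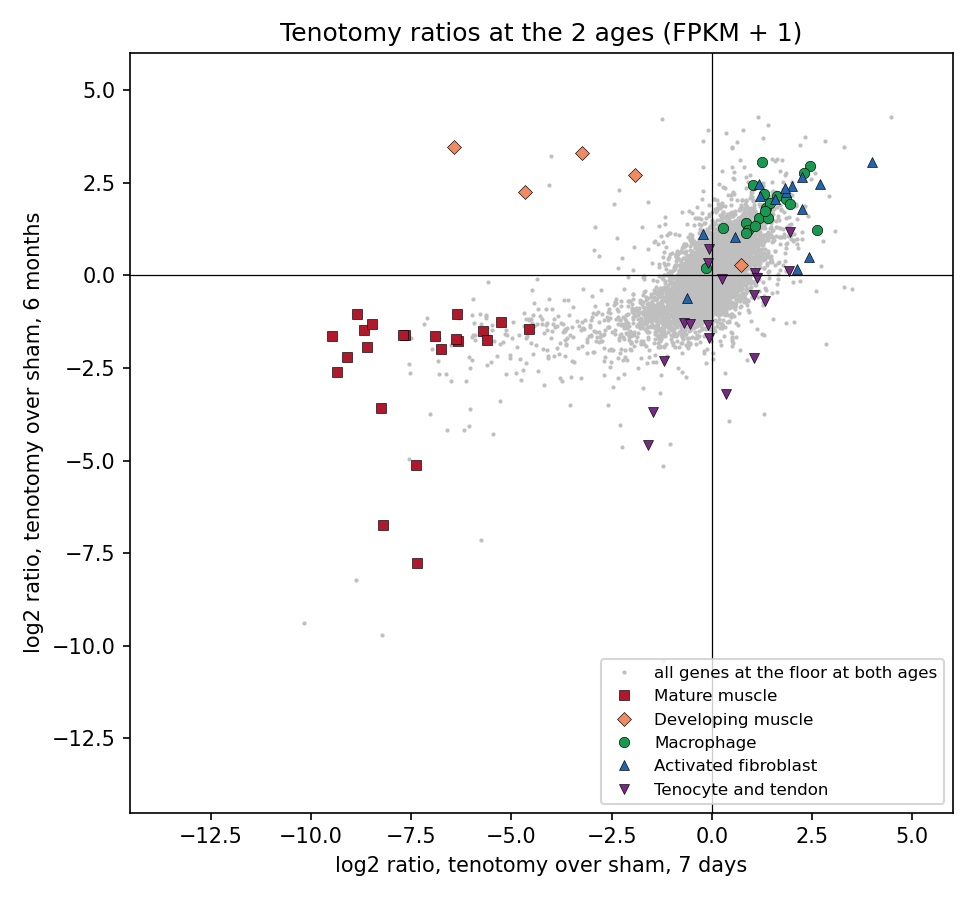
Log2 ratio of tenotomy over sham at 7 days (horizontal) against 6 months (vertical) for the 8348 genes at or above 5 FPKM at both ages, each point a gene. Coloured symbols mark gene lists; macrophage and activated fibroblast genes lie mostly at upper right, the mature muscle genes at lower left, and Myh8 (-6.44 and 3.46) with other developing muscle genes at upper left.

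The sham libraries of the ages were set side by side as levels only, because they come from separate tables. Col1a1 stood at 22438 FPKM at 7 days and 5578 at 6 months, Tnmd at 301.1 and 36.9 FPKM, Tppp3 at 227 and 59.0 FPKM, and Igf2 at 858 and 7.96 FPKM. Chad stood at 27.1 and 936 FPKM, Comp at 112 and 1443 FPKM, Prg4 at 31.9 and 544 FPKM, Spp1 at 19.4 and 1131 FPKM and Ibsp at 1.06 and 348 FPKM. Other matrix genes of cartilage and tendon stood higher at 7 days, with Col2a1 at 110 and 77.0 FPKM, Col11a2 at 182 and 22.1 FPKM and Fmod at 740 and 578 FPKM. The genes of this paragraph were picked from the lists as examples. The median gene of the tenocyte list ranked at percentile 97.7 of its library at 7 days and 97.8 at 6 months, that of the proliferation list at 60.4 and 49.4, and that of the PI3K-Akt list at 74.7 and 79.1.

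**Figure D3:**
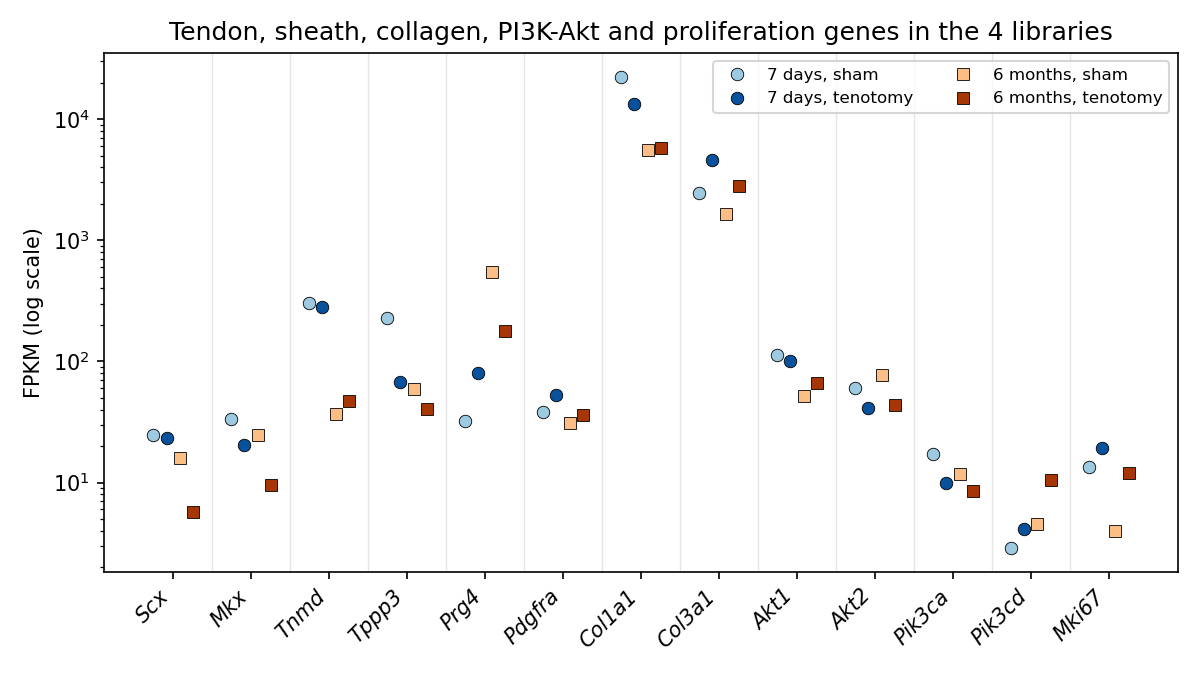
FPKM on a log axis of genes chosen before the data were examined, with circles for 7 days, squares for 6 months, light symbols for sham and dark symbols for tenotomy, each symbol 1 library. Scx stood at 24.8 and 23.3 FPKM at 7 days and at 15.9 and 5.70 FPKM at 6 months, and Akt1 and Akt2 differed by less than 2-fold between sham and tenotomy at both ages.

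In GENCODE release M21 on the mm10 assembly, Scx lies on chromosome 15 from 76457452 to 76459458 on the plus strand, and its locus in the tables was shared with other entries, so reads of overlapping genes may enter its value. The same limit holds for Ckm, Mest, Myh7, Myoc, Aspn, Chad, Prg4, Has2, Fgf1, Igf2, Irs2, Ccna2, Acp5, Il1b, Timp3, Timp4, Ltbp2 and Runx2 among the genes named by the rule. Tppp3 lies on chromosome 8 from 105467493 to 105471526 on the minus strand, Prg4 on chromosome 1 from 150449412 to 150466165 on the minus strand, and Tnmd on chromosome X from 133850980 to 133865577 on the plus strand. Mmp13 lies on chromosome 9 from 7272514 to 7283331 on the plus strand, and Mest on chromosome 6 from 30723547 to 30748465 on the plus strand. Spp1 and Ibsp are neighbours on chromosome 5, from 104435118 to 104441050 and from 104299171 to 104311469, both on the plus strand. The myosin genes Myh3 (67078300 to 67102291), Myh1 (67200052 to 67224575) and Myh8 (67277124 to 67308634) lie in a cluster on chromosome 11 on the plus strand.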

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

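The tests of library scale, of slow against fast muscle genes, of dilution and of the part of the tendon collected were chosen only after the results were seen; those of paralogs and of denervation genes were written before. The dilution comparison was first made with collagens in place of the tenocyte list, which would have argued against dilution, and was replaced after its value was seen; the value for denervation genes was set against its interquartile range only after it was seen, and by its median alone it would have argued against that explanation. Each result in the next paragraph stands out because its tenotomy ratio passed the size rule upward at one age and downward at the other, or, for a list, because its median stood apart from matched random lists in opposite directions; these differences rest on 1 library per group and were not tested.

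The median of the cartilage list was 2.63 higher at 7 days than at 6 months on the log2 scale, from 1.35 (10 genes) to -1.29 (7 genes). Gene by gene the median difference was 1.07 over 11 genes. With a floor of 20 FPKM, where few genes remained, the 7-day median was -1.77 and the median difference 0.15. The opposite directions thus depended on the floor, though Acan, above that floor, had log2 ratios of 2.01 at 7 days and -0.17 at 6 months. The median of the developing muscle list was -3.23 at 7 days and 2.25 at 6 months, a difference of -5.48 between 5 and 7 genes measured; gene by gene the median difference was -4.63. Among its members the difference was -9.90 for Myh8, -6.91 for Myh3, -6.53 for Myog and -4.63 for Tmem8c. Mature muscle genes were lower at 7 days too (median -7.51), from 6.41% of the FPKM of ordinary genes after sham to 0.0154% after tenotomy. The lower developing muscle genes at 7 days therefore cannot be told apart from less muscle in the tenotomy pool. Spp1 differed by 4.70 (19.4 to 146 FPKM at 7 days, 1131 to 311 at 6 months). Galnt15 differed by 5.03 (1.74 to 5.69 FPKM, then 76.4 to 4.80). Prg4 differed by 2.89. Hmga1 differed by -5.45, a value that is uncertain where similar sequences share reads. Akr1b3 differed by -7.22, with values of 0.00149 FPKM after tenotomy at 7 days and 0.00217 after sham at 6 months, in a locus shared with another entry.

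Respiratory chain genes had a median of -1.58 and glycolysis genes of -0.71 after tenotomy at 7 days. Muscle in the sham library is a candidate source: paralogs used in most tissues (Cox6a1, Cox8a, Eno1 and others) had a median of 0.15, while the paralogs of muscle had a median of -5.36. A lower scale of the whole tenotomy library is argued against, for the values as deposited, by the median of 0.0135 over all genes tested. Any scaling between the libraries is not given and may itself have set that median. An effect of the injury on tendon cell metabolism was not tested apart from this.

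At 6 months, slow-fibre muscle genes had a median of -4.96 and fast-fibre genes of -1.46. A single lower share of the same muscle would shift both alike, and the gap of -3.51, with interquartile ranges that did not overlap, argues against it. Muscle of another kind in the tenotomy pool stays open; at 7 days the gap was 0.34, but the pool and the operation are the same library, so they cannot be told apart. A denervation or injury response of the muscle also stays open: its genes had a median of -0.72, with Chrna1 at 1.98 and Runx1 at 1.35 but Ankrd1 at -1.83, and the bound set for this test left out that muscle genes as a whole were lower. The higher Myog and Myh8 at 6 months were not part of that test.

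Cartilage and bone-forming genes together had a median of -1.44 at 6 months. Dilution of tendon RNA by incoming cells stays open: the tenocyte list lay 0.44 above them, with overlapping interquartile ranges. That list ran from -4.59 to 1.17 and holds Chad and Comp, which are genes of cartilage too, so its closeness does not decide the question. Lower collagens were also part of what dilution was taken to predict, but collagens had a median of 0.33. They could also come from incoming fibroblasts. Collection of another part of the tendon also stays open, since the distal stump was the part taken after tenotomy. Whether that stump held more or less fibrocartilage than the sham tendon was not measured. The cartilage list had a median of 1.35 at 7 days, which does not bear on the adult pools. The part collected and the operation are the same library, so they cannot be told apart. A true loss of expression after injury in adults is the biological alternative and was not tested.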

How the results depend on the processing

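Of the alternatives, the scaling without muscle genes and small RNAs and the removal of genes 8-fold lower at 7 days were chosen after seeing the data. With 1 library per group nothing could be left out in turn, and pairing by animal was not possible because each group holds 1 pool. An analysis of tenotomy against sham paired by age was not run. Of 878 list values under alternatives, 813 kept their direction and their side of the percentile threshold, 20 fell back inside it and 10 passed it. In 35 the median changed sign: 34 belonged to 18 results that stood inside the threshold, among them the PI3K-Akt list at each age under another scaling, the tenocyte list at 7 days without its largest member and the erythroid list at 6 months. Of 3284 values of named genes, 3206 kept both, 52 fell below 2-fold, 17 passed it and 9 within 2-fold changed sign. The list that had stood apart and changed sign was the cartilage list at 7 days, -1.77 with a floor of 20 FPKM, where fewer genes enter. With that floor the proliferation, cytokine, mural and erythroid lists at 7 days and the endothelial list at 6 months no longer stood apart, nor did the proliferation, macrophage, activated fibroblast, cartilage, mural and erythroid lists in the difference between ages. At 6 months the tenocyte list no longer stood apart with a floor of 1 FPKM, with no floor or without its largest member, nor did the collagens without theirs or the interferon list with a pseudocount of 5 FPKM or scaled without muscle genes and small RNAs. The erythroid list at 7 days and the mural list in the difference also lost this without their largest member, and the activated fibroblast list in the difference with the pseudocount of 5. Rescaling FPKM to a common sum moved the median log2 ratio of all genes at 7 days to 0.17, and 48.8% of genes past 2-fold were then higher, against 34.96%. That rescaling also raised the values against the floor and pseudocount, with 11532 genes against 9424 at the floor, so this change is not one of scaling alone. Scaling without muscle genes and small RNAs moved the median at 6 months to 0.17, with 61.8% higher against 44.8%. Relative to these shifts, the activated fibroblast, macrophage and mature muscle lists kept their direction at both ages. Of 72 gene counts, 49 stayed within 1.5 times the main count.

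The other counts follow. For genes higher at 7 days (523), 255 with a pseudocount of 5 FPKM, 276 with a floor of 20 FPKM, 1036 with FPKM rescaled to a common sum and 3 by the authors' call. For genes lower at 7 days (973), 540 with the floor of 20 and 87 by the authors' call. For genes higher at 6 months (866), 420 with the pseudocount of 5, 354 with the floor of 20, 1333 with a floor of 1 FPKM, 1333 with no floor and 0 by the authors' call. For genes lower at 6 months (1067), 619 with the pseudocount of 5, 622 with the floor of 20 and 0 by the authors' call. For ratios higher at 7 days than at 6 months (568), 234 with the pseudocount of 5, 204 with the floor of 20, 950 with the floor of 1, 986 with no floor and 1007 with the common sum. For ratios lower at 7 days (889), 427 with the pseudocount of 5, 421 with the floor of 20, 1481 with the floor of 1 and 1540 with no floor. A higher pseudocount or floor leaves fewer low genes past 2-fold by construction; other causes were not tested.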

Other observations

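The test of imprinted genes and that of histone genes were written before their results were seen; the value for imprinted genes was set against its interquartile range only afterwards, and by its median alone it would have argued against a shared change. Replication-dependent histone genes were among the highest ratios at 6 months. Of 42 histone entries measured there, 26 were at least 2-fold higher and none lower, and Hist1h3a, Hist1h2bj and Hist1h3b were listed at 0 after sham and at 18.2, 13.2 and 11.4 FPKM after tenotomy. Such high ratios prompted the list and remain in it, so its median is not independent of what was first seen. Copies of histone genes share sequence and are short, so single values are uncertain and those near the floor rest on few fragments. Their median of 1.502, beside a median of 1.28 for the proliferation list, is consistent with more cells in S phase after tenotomy in adults, as a hypothesis; at 7 days the median of 46 histone entries was 0.38.

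Mest was higher at both ages (105 to 754 FPKM at 7 days, 5.58 to 79.6 at 6 months). Other imprinted growth genes did not clearly follow it at 7 days: the lower of their medians at the ages was -0.0159, with Dlk1 at -1.42 and Plagl1 at 1.02, and this left open whether they move together. At 6 months their median was 0.65, with Igf2 at 2.23, Plagl1 at 1.44 and Grb10 at 1.22. C1qtnf3, a secreted protein gene of fibroblasts and cartilage, was also higher at both ages (120 to 599 FPKM and 7.74 to 116 FPKM).

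Hair keratin genes were present in the 7-day sham library. Of 73 listed, all 42 measured were at least 2-fold lower after tenotomy (median -3.89), and none reached 5 FPKM at 6 months. The authors' deposited table called 9 of them significant at 7 days, and only 3 of the 22 mature muscle genes, although Ckm stood at 892 and 0.25 FPKM there with a q-value of 0.998. Of its 87 genes called lower, 71 were listed at 0 after tenotomy.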
